A study of Homo sapiens with 8 samples.

How the data were processed

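Gene expression was measured on 8 Affymetrix GeneAtlas arrays, 1 for each combination of treatment and time. NS-SV-AC, an immortalised line of human salivary gland acinar cells, was exposed either to TNF-α at 20 ng/ml or to bovine serum albumin (BSA), the control protein, and RNA was taken after 2, 6, 12 and 24 h. Total RNA was extracted with TRIzol, and 10 ng per array was amplified and biotin-labelled with a 3′ IVT kit, which primes from the 3′ end of transcripts. There were 4 arrays per treatment and no replicate of any treatment at any time. The labels give no scan date and no batch, so none could be examined.

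The deposited values are on the log2 scale, 1 per probe set and array, and per the submitters' processing notes they were made with RMA. RMA corrects the background, makes the arrays' distributions equal by quantile normalisation and summarises the probes of each probe set. The RMA software, its version and any filter are not given in the sources used here. The values were checked against this: all 8 columns held 49386 probe sets, with medians from 4.33 to 4.36 and a range typical of log2 RMA values. The quartiles were 3.37 to 3.42 and 6.40 to 6.54 on 7 arrays and 3.51 and 6.22 on TNF-α at 24 h. RMA makes distributions equal for probes and not for probe sets, so these values do not show whether the 8 arrays were normalised together. All columns differed from each other. No further normalisation, filter or pseudocount was applied for the values reported first. Arrays give no read depth, so the number of arrays limits the precision.

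Probe sets were paired with gene symbols by the platform's own annotation, with symbols checked through Entrez identifiers against a RefSeq gene table. Of the identifiers, 18180 matched the table and 62 did not. 45253 probe sets had 1 gene symbol and were used. Another 1327 had several symbols, 2713 had none listed and 93 were array controls, and these were left out of the gene tests. Where a gene had more than 1 probe set (11822 genes, 64.8%), the probe set with the highest mean over the 8 arrays stood for it. This choice does not use the labels, but 4 of the 8 arrays are TNF-α arrays, so it can favour probe sets that are high with TNF-α. Differences of single genes are for that probe set unless the mean of probe sets is named. This gave 18239 genes. No genome coordinates were used.

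Genes changed by TNF-α were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with treatment as the coefficient and time as a factor, so that each TNF-α array was compared with the BSA array of its own time. This left 3 residual degrees of freedom, and 2 when the arrays of 1 time were left out. p-values were adjusted by the Benjamini-Hochberg method over all genes, and an adjusted p under 0.05 counted as a change. Because each time had 1 array per treatment, these p-values measure the spread between these arrays, which holds both array noise and any change of the effect with time. The words rose and fell are kept for genes and lists past this threshold, and the other values are given without a test. Dependence on time was tested with a further limma model holding treatment, log2 of the hours and their product, with 4 residual degrees of freedom, which also gave the slope with time in each arm. At single times the difference between the TNF-α and BSA arrays was taken, and genes at least 2-fold apart were counted without any test. Correlations between times were computed across genes.

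The 40 gene lists held 633 symbols, of which 583 were measured. Their shift was tested with camera (limma, preset correlation of 0.01), adjusted over the 40 lists, and again with an estimated correlation and with fry. Camera compares a list with all other genes. Fry asks whether the genes of a list move, on balance, in 1 direction, and compares it with no other genes. Members past the threshold were counted with p adjusted over all genes and adjusted over the list alone. At each time, a list's median difference was ranked among those of 10000 random lists of the same size matched on mean expression in 20 bins, and is given as a percentile.

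The samples' groups, the models, the thresholds, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined. The genes named are the 15 largest rises and 10 largest falls past the threshold, or, where fewer than 5 pass, the 15 with the smallest p, said not to pass. For the dependence on time they are the 6 with the smallest p where fewer than 5 pass, and for the slopes the 5 largest in each direction past the threshold. At each single time the 5 largest differences in each direction are named, and for each list described by its members up to 4 of them. NFKBIA, TNFAIP3, CXCL8, CXCL10, ICAM1, IL6, TNF, TNFRSF1A, MMP9, AQP5 and SOD2 are always named. After the 24 h TNF-α array was seen to stand apart, the same rule was also applied to the planned fit without the 24 h pair of arrays, and array quality weights (limma arrayWeights) were added as an alternative. Which 19 of the 40 lists are described by their members was chosen after values were seen, and the result of each of the 40 is given.

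The test was checked on simulated data with 50 changed genes of each size among 18239. With 4 times it recovered 78% of genes changed 2-fold, 98% of those changed 4-fold, and 100% of those changed 8-fold or 16-fold, with 17 false calls among 205. With the 3 times from 2 to 12 h it recovered 98%, 100%, 100% and 100%, with 12 false calls among 211. Each simulated change was the same at all times, and the noise was independent between arrays. Effects that vary with time and an array of poor quality were not simulated, so these shares do not carry over to the real data. There CXCL8, with a mean difference of 5.66 over the 4 times, did not pass with limma (adjusted p = 0.378). The alternatives tried were the mean of a gene's probe sets, all probe sets tested singly, only genes at or above the median level, quantile normalisation again, centring of the arrays, eBayes with trend and robust settings, other forms of the time term, other fold thresholds, rank correlation and the omission of each time in turn. Other splits of the arrays into groups of the same size were also fitted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.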

Results

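The data are expression profiles of NS-SV-AC cells, an immortalised line from the acini of a human salivary gland, the units that secrete saliva. Cells received TNF-α, an inflammatory cytokine, or BSA, the control protein, for 2, 6, 12 or 24 h, and 1 array was measured for each, so there were 4 arrays per treatment and no replicate at any time. Values are log2, and differences are TNF-α minus BSA. The 7 arrays other than TNF-α at 24 h correlated with each other across the 18239 genes with r from 0.962 to 0.994. The TNF-α array at 24 h had a mean r of 0.925 with the others. On that array the 3′ end of the GAPDH transcript read 6.28 above its 5′ end, against 0.20 to 0.37 on the other 7 arrays, and for ACTB the gap was 6.88 against 2.59 to 3.47. A wide gap between the 3′ and 5′ ends is a usual sign of degraded RNA.

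**Figure D1:**
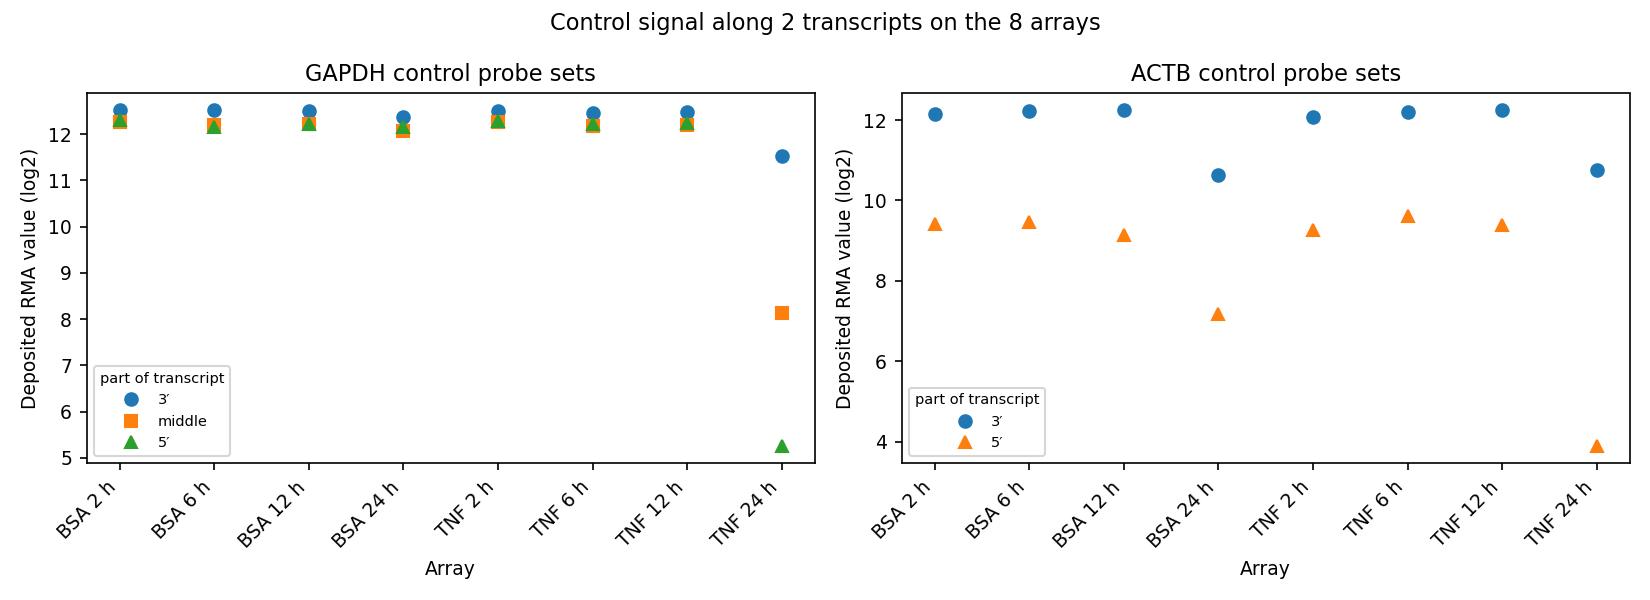
Deposited log2 value of the control probe sets for the 3′, middle and 5′ parts of GAPDH (left) and the 3′ and 5′ parts of ACTB (right) on each of the 8 arrays, 1 point per probe set. On TNF-α at 24 h the GAPDH gap between 3′ and 5′ was 6.28, against at most 0.37 on the other arrays.

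Which genes did TNF-α change in these cells? Over the 4 times NFKBIA, which encodes the inhibitor that holds NF-κB in the cytoplasm, rose by 3.27 ± 0.09 (SE, 4 pairs of arrays), TNFAIP3, which encodes the ubiquitin-editing feedback inhibitor A20, rose by 6.94 ± 0.33, and PTGER4, a receptor for prostaglandin E2, rose by 3.38 ± 0.15 (1.86 as the mean of its 2 probe sets, without passing). All 3 were higher in 4 of 4 pairs. Over 2, 6 and 12 h many more genes passed. The leukocyte attractants CXCL8 (6.48 ± 0.66, SE, 3 pairs), CCL20 (5.76 ± 0.65) and CCL2 (5.65 ± 0.18) rose, as did the cytokine IL6 (4.02 ± 0.45), the adhesion molecules VCAM1 (3.81 ± 0.28) and ICAM1 (3.63 ± 0.41), and CLDN1, a tight junction protein (4.40 ± 0.51). Over the 4 times, the mean of probe sets gave 3.97 for CXCL8, 2.28 for IL6 and 2.52 for CLDN1, where the brightest gave 5.66, 3.57 and 4.19. For VCAM1 it gave 3.33 in place of 3.82, and for ICAM1 3.11 in place of 3.02. SOX2, a transcription factor of progenitor cells, fell by 2.75 ± 0.17 on 1 of its 3 probe sets (the other 2 lay between −0.29 and 0.09), and ID1, an inhibitor of basic helix-loop-helix transcription factors, fell by 2.69 ± 0.26.

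With limma 3 genes passed over the 4 times, 3 higher and 0 lower, with adjusted p = 0.00365 for NFKBIA, 0.0166 for PTGER4 and 0.0184 for TNFAIP3. At an unadjusted p under 0.05 there were 1369 genes, where chance gives 912. Leaving out 1 time changed the count: without the 24 h pair it was 67 (58 risen, 9 fallen, 2554 at an unadjusted p under 0.05), with the 3 genes above among them, and without the 2 h, 6 h or 12 h pair it was 0. NFKBIA, PTGER4 and TNFAIP3 were then 3.22, 3.48 and 6.63 higher without 2 h (adjusted p = 0.0798 each), 3.32, 3.22 and 6.76 without 6 h (0.0845, 0.0845 and 0.241) and 3.31, 3.36 and 7.15 without 12 h (0.117, 0.263 and 0.263). Each of these fits of 3 pairs had 2 residual degrees of freedom in place of 3. With the mean of each gene’s probe sets in place of the brightest, NFKBIA alone passed, while PTGER4 was 1.86 higher (adjusted p = 0.0514) and TNFAIP3 5.46 (0.194). Of the 58 genes that rose from 2 to 12 h, 46 were also higher at 24 h and 29 at least 2-fold. Of the 9 that fell, 3 were also lower at 24 h and 0 at least 2-fold.

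The genes with the next smallest p over the 4 times did not pass, although each was higher in 4 of 4 pairs. They were VCAM1 (3.82 ± 0.26, adjusted p = 0.0763), GRAMD2B (2.15 ± 0.16), the transcription factor KLF4 (3.58 ± 0.28), ZFP36L2, an RNA-binding protein that promotes mRNA decay (1.09 ± 0.09), the membrane-bound chemokine CX3CL1 (1.98 ± 0.17), ZNF697 (1.36 ± 0.13), MRNIP (0.81 ± 0.08), FOSL2, an AP-1 subunit (1.61 ± 0.17), KLRC1 (0.94 ± 0.10), the scavenger receptor OLR1 (2.31 ± 0.25), KLF10 (0.93 ± 0.10) and SIX4 (1.34 ± 0.15). Without the 24 h pair 11 of these 12 passed, and OLR1 had an adjusted p of 0.0550. With the mean of each gene's probe sets over the 4 times some were smaller: ZFP36L2 was 0.59 higher, CX3CL1 1.10, ZNF697 0.51, MRNIP 0.21 and FOSL2 0.94. OLR1 was 2.39 higher, and KLRC1 and SIX4 were unchanged.

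Among the largest rises from 2 to 12 h TNFAIP3 led with 7.22 ± 0.29. TNFRSF9, a co-stimulatory receptor also called 4-1BB, rose by 4.63 ± 0.37, and at 24 h it was 0.59 higher. EDN1, the precursor of the vasoconstrictor endothelin, rose by 3.69 ± 0.22 and TNFAIP2 by 3.58 ± 0.21; at 24 h they were 0.83 and 0.87 higher. The matrix glycoprotein TNC rose by 3.57 ± 0.35, KLF4 by 3.60 ± 0.31, PTGER4 by 3.45 ± 0.15 and the neuronal pentraxin NPTX1 by 3.32 ± 0.38, and these 4 stayed at least 1.58 higher at 24 h. Adjusted p ranged from 0.00122 for CCL2 to 0.0496 for CLDN1 among the 15 largest rises. Some sizes depend on the probe set. Over the 4 times the brightest probe set and the mean of probe sets gave 2.90 and 1.35 for TNFAIP2, 3.15 and 2.01 for TNC, and 2.89 and 1.56 for NPTX1. For KLF4 they gave 3.58 and 2.49, and for EDN1 2.97 and 2.99.

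All 9 genes that fell from 2 to 12 h are named. After SOX2 (adjusted p = 0.00828) and ID1 (0.0302) the falls were smaller: the zinc finger genes ZNF708 (−1.14 ± 0.08) and ZNF92 (−0.77 ± 0.08), the semaphorin SEMA6D (−0.92 ± 0.08), the transcription factors ISL1 (−0.89 ± 0.10) and KLF2 (−0.80 ± 0.09), RASL11B (−0.86 ± 0.09) and PPP1R3C, a subunit that targets protein phosphatase 1 to glycogen (−0.86 ± 0.08). ID2, a relative of ID1, was lower at 2, 6, 12 and 24 h, by −1.65, −2.43, −3.30 and −1.17, and did not pass (adjusted p = 0.0516 from 2 to 12 h). All 3 probe sets of ID1 were lower from 2 to 12 h. SOX2 has 3 probe sets; the brightest gave the values above, and the other 2 lay between −0.29 and 0.09 at 2, 6 and 12 h. Of the 4 probe sets of SEMA6D, 2 were lower at 2 h, 1 at 6 h and 2 at 12 h.

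**Figure D2:**
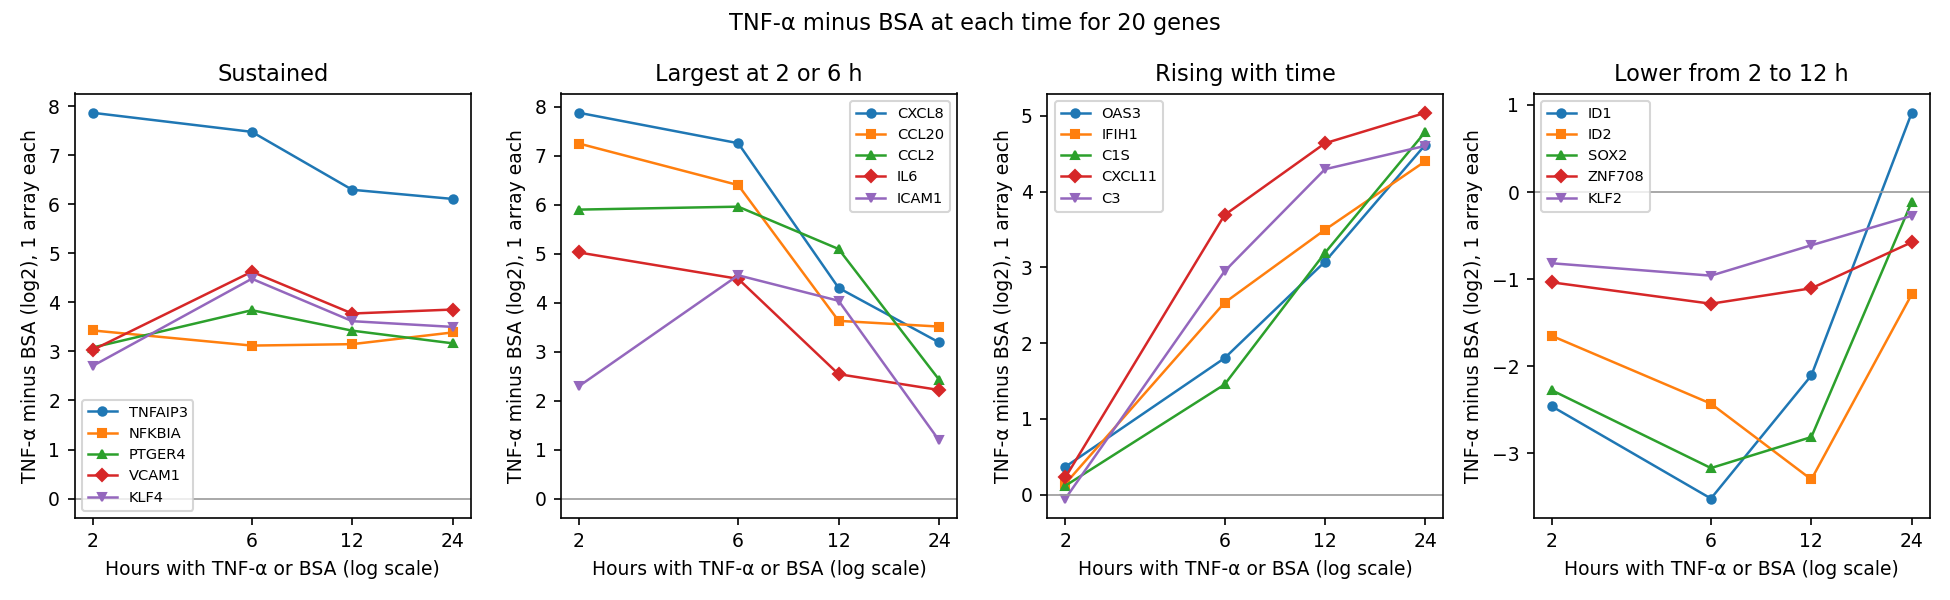
TNF-α minus BSA (log2, y axis) at 2, 6, 12 and 24 h (log time axis) for 20 genes, each point from 1 array per treatment. TNFAIP3, NFKBIA and PTGER4 were at least 3.08 at the 4 times, OAS3 and C1S were 0.37 and 0.12 at 2 h and 4.62 and 4.79 at 24 h, and ID1 and SOX2 lay between −3.52 and −2.11 from 2 to 12 h.

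Which gene groups moved together? The NF-κB inhibitors and subunits, chemokines, cytokines, adhesion molecules, interferon-stimulated genes and class I antigen presentation genes were called up by camera against the other genes, and the proliferation and oxidative phosphorylation groups down by small amounts. With an estimated correlation camera called 0 lists, where adjusted p of the 24 called lists ranged from 0.249 to 0.594. That form uses only the residual degrees of freedom, 3 over the 4 times and 2 without the 24 h pair, so it could call few lists. Its lost calls do not show that a list stayed unchanged, while the preset form rests on an assumed correlation of 0.01. Over the 4 times camera called 24 of the 40 lists, 17 up and 7 down. Without the 24 h pair it called 15, 12 up and 3 down, which also became 0 with an estimated correlation. Fry called 3 over the 4 times (the NF-κB, CC and CX3C chemokine and AP-1 lists) and 0 without the 24 h pair. In the neutrophil CXC, the CC and CX3C and the cytokine lists a few members carried the shift, with means from 2 to 12 h of 1.41, 1.75 and 0.66 and medians of 0.14, 0.08 and 0.13. At 24 h the median difference over all genes was 0.20 as deposited, 0.12 after centring and 0.03 after quantile normalisation again, so the 24 h medians below are given with their percentile among matched random lists. The quartiles of the 24 h array lay closer together in TNF-α (3.51 and 6.22) than in BSA (3.37 and 6.54).

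NF-κB feedback and signalling was the list with the smallest p. Of 15 measured members, 2 rose over the 4 times (11 adjusted over the list alone), and from 2 to 12 h 7 rose (13 adjusted over the list alone). Its median difference was 2.00, 2.65, 2.09 and 0.97 at 2, 6, 12 and 24 h, at the 100th percentile each time. Besides TNFAIP3, NFKBIA and TNFAIP2, NFKBIE, another inhibitor of NF-κB, rose from 2 to 12 h by 2.54 ± 0.13, and the nuclear inhibitor NFKBIZ, which did not pass, was 3.76 higher at 2 h and 1.64 at 12 h. Camera gave adjusted p = 1.72e-16 over the 4 times and 1.43e-23 without the 24 h pair. The call was lost with adjusted p = 0.249 and 0.481 with an estimated correlation.

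Chemokines were prominent among the largest differences. In the list of CXC chemokines of neutrophils (7 measured) CXCL8 rose from 2 to 12 h, and 0 of 7 passed over the 4 times (2 adjusted over the list alone, with or without the 24 h pair). CXCL8 was 7.88, 7.26, 4.30 and 3.19 higher at 2, 6, 12 and 24 h, CXCL2 was 4.05 higher at 2 h and 0.82 at 12 h, and CXCL3 was 1.85 higher at 2 h and 0.09 at 12 h. The list's medians were 0.31, 0.09, 0.09 and 0.35 (24 h percentile 95.3). It had adjusted p = 0.00373 by camera, and adjusted p = 0.249 with an estimated correlation. In the interferon-inducible CXC chemokines, attractants of T cells (3 measured, 0 past the threshold, 2 adjusted over the list alone), CXCL10 was 2.20, 6.82, 6.96 and 1.74 higher, CXCL11 was 0.23, 3.69, 4.64 and 5.04 higher, and CXCL9 differed by at most 0.58. For this list, with medians of 0.23, 3.69, 4.64 and 1.74 (24 h percentile 99.9), camera gave adjusted p = 0.00663, and adjusted p = 0.249 with an estimated correlation. The median level in BSA was 2.85 for the neutrophil and 3.50 for the interferon-inducible list, under the lower quartile of all genes, 3.74. Exact sizes of differences from levels near the background are uncertain. Of 9 CC and CX3C chemokines 0 passed over the 4 times and 3 rose from 2 to 12 h (CCL20, CCL2 and CX3CL1), with 3 adjusted over the list alone in both. CCL5 was 2.57 higher at 6 h and 4.18 at 12 h without passing. This list, with medians of 0.13, 0.07, 0.23 and 0.41 (24 h percentile 93.4), had adjusted p = 0.00159 by camera, 0.0187 by fry, and adjusted p = 0.249 with an estimated correlation.

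Of 20 cytokines and growth factors of inflammation, 0 rose over the 4 times (4 adjusted over the list alone) and 1, IL6, from 2 to 12 h (8 adjusted over the list alone). IL6 was 5.02 higher at 2 h and 2.22 at 24 h, LIF, a cytokine of the IL-6 family, was 2.69 higher at 2 h and 0.21 at 12 h, and IL32 went from 1.14 at 2 h to 3.91 at 12 h. TNF itself was 0.81, 0.79, 0.20 and 0.36 higher and did not pass. With list medians of 0.13, 0.19, 0.18 and 0.48 (24 h percentile 99.8), camera gave adjusted p = 3.74e-06, and adjusted p = 0.249 with an estimated correlation. Of 9 adhesion molecules 0 passed over the 4 times and 2, VCAM1 and ICAM1, rose from 2 to 12 h, with 4 adjusted over the list alone in both. ICAM1 was 4.56, 4.04 and 1.19 higher at 6, 12 and 24 h, and the hyaluronan receptor CD44 was 0.22, 1.86, 2.83 and 4.84 higher without passing. The adhesion list, with medians of 0.21, 0.53, 0.51 and 1.19 (24 h percentile above 99.9), had adjusted p = 0.000648, and adjusted p = 0.249 with an estimated correlation.

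The AP-1 and immediate early genes, transcription factors and signalling genes that respond within hours, had 22 measured members. Over the 4 times 0 passed (7 up and 2 down adjusted over the list alone), and from 2 to 12 h 7 rose and 1 fell (11 and 2 adjusted over the list alone). KLF4 and FOSL2 rose from 2 to 12 h, as did JUN, the core AP-1 subunit (1.57 ± 0.07), and IER3 (2.11 ± 0.23). Rose here means higher in TNF-α than in BSA over these 3 times, not an increase with time. Against BSA at 2 h the list's median in BSA was −0.61 at 6 h and −1.06 at 12 h. IER3 in BSA read 8.32, 6.19 and 5.32 at 2, 6 and 12 h. At 24 h JUN was −1.20. The list, with medians of 0.44, 0.31, 0.60 and 0.25 (24 h percentile 74.0), had adjusted p = 9.13e-05 by camera, 0.0467 by fry, and adjusted p = 0.249 with an estimated correlation.

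Interferon-stimulated genes, many of them antiviral effectors, were called up by camera with adjusted p = 1.92e-14 over the 4 times and 3.51e-18 without the 24 h pair. These became adjusted p = 0.249 and 0.481 with an estimated correlation. Their median difference was 0.10 at 2 h, 0.89 at 6 h, 1.97 at 12 h and 2.58 at 24 h, each at the 100th percentile, and of 28 measured members 3, 13, 24 and 21 were at least 2-fold higher. Member by member 0 passed over the 4 times (12 adjusted over the list alone), and from 2 to 12 h IRF1 alone passed (15 adjusted over the list alone). IRF1, a transcription factor, rose by 2.44 ± 0.11 and was 2.61 higher at 2 h and −0.19 at 24 h. The GTPase GBP1 was 2.24, 5.95, 4.59 and 3.01 higher, and the RNA sensors IFIH1 (0.15, 2.53, 3.50 and 4.40) and RIGI (0.57, 3.23, 3.06 and 4.34) were higher from 6 h on. At 24 h the values come from the array whose GAPDH gap was 6.28.

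Class I antigen presentation, complement and TNF and TNF receptor superfamily genes were also called up by camera, and lost the call with adjusted p = 0.306, 0.249 and 0.249 with an estimated correlation. Of 15 class I genes 0 passed (1 adjusted over the list alone; 0 and 4 from 2 to 12 h), with medians of 0.04, 0.64, 0.94 and 0.89 (24 h percentile 100). The peptide transporter TAP1 was 0.93 higher at 2 h and 2.31 at 12 h, and HLA-F 0.10 and 1.99. For class I camera gave adjusted p = 1.26e-05, and adjusted p = 0.306 with an estimated correlation. Of 17 complement and acute phase genes 0 passed over the 4 times (6 adjusted over the list alone), and PTX3 rose from 2 to 12 h by 2.43 ± 0.28 (6 adjusted over the list alone). C3, the central complement component, was −0.05, 2.95, 4.30 and 4.61, and the acute phase proteins SAA1 and SAA2 were 2.91 and 3.36 higher at 12 h. The complement list had medians of 0.02, 0.25, 0.33 and 0.35 (24 h percentile 95.1). Adjusted p was 0.000577 for this list, and adjusted p = 0.249 with an estimated correlation. Of 12 genes of the TNF and TNF receptor superfamily 0 passed over the 4 times (2 adjusted over the list alone), and TNFRSF9 and the death receptor TNFRSF10B (0.82 ± 0.07) rose from 2 to 12 h (4 adjusted over the list alone). FAS and CD40 were 1.94 and 2.04 higher at 12 h. TNFRSF1A, the main TNF-α receptor, was −0.02, 0.36, 0.67 and −0.64. The superfamily list had medians of 0.10, 0.39, 0.58 and 0.29 (24 h percentile 70.8). Adjusted p was 0.00567, and adjusted p = 0.249 with an estimated correlation. Of 19 apoptosis genes and inhibitors 0 passed (1 adjusted over the list alone; 0 and 3 from 2 to 12 h). CFLAR, which blocks caspase-8, was 1.91 higher at 12 h, and the pro-apoptotic BID and BBC3 were 1.70 and 1.03 higher. Apoptosis medians were −0.01, 0.09, 0.30 and 0.38 (24 h percentile 91.6). Camera gave the list adjusted p = 0.0287, and adjusted p = 0.419 with an estimated correlation.

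**Figure D3:**
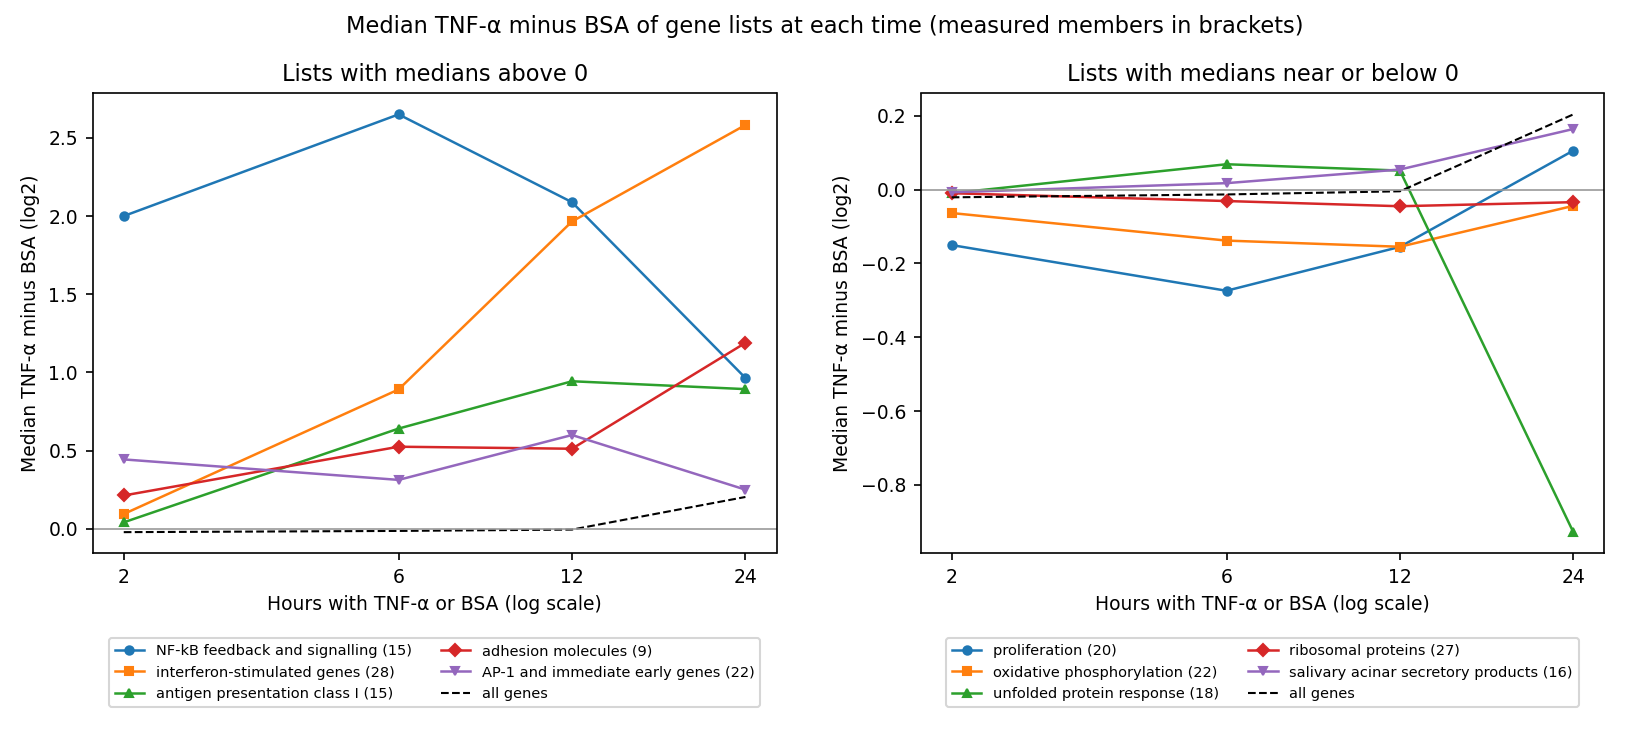
Median TNF-α minus BSA (log2, y axis) of 10 gene lists and of all genes (dashed) at each time (log axis), with the number of measured members in brackets. The NF-κB list was highest at 6 h (2.65), the interferon-stimulated list at 24 h (2.58), and the unfolded protein response list was −0.93 at 24 h and between −0.01 and 0.07 before.

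Proliferation genes were called down by camera, by small amounts (adjusted p = 0.00175, and 1.61e-05 without the 24 h pair). The call was lost with adjusted p = 0.249 and 0.481 with an estimated correlation. Of 20 members 0 passed in either fit, also adjusted over the list alone, and the median was −0.15, −0.27, −0.15 and 0.11 at 2, 6, 12 and 24 h (24 h percentile 46.0, and −0.10 relative to all genes). CDC20 was −0.55 and the mitotic kinase PLK1 −0.59 at 6 h. Oxidative phosphorylation genes (22 members, 0 passed, 0 adjusted over the list alone) had medians of −0.06, −0.14, −0.15 and −0.04 (24 h percentile 18.0, and −0.25 relative to all genes), and 4 were at least 2-fold lower at 24 h. SDHA, a subunit of succinate dehydrogenase, was −0.31 at 6 h and at 12 h, and NDUFS3 of complex I was −0.34 and −0.33. Camera gave adjusted p = 0.00159, and adjusted p = 0.249 with an estimated correlation. Among 9 DNA methyltransferases and TET enzymes, which add and oxidise DNA methylation, 0 passed (0 adjusted over the list alone; 3 fallen adjusted over the list alone from 2 to 12 h). TET1 was −0.47, −1.30, −1.79 and −0.69 and TET2 was −0.28, −0.71, −1.17 and 0.71. The list medians were −0.16, −0.22, −0.06 and −0.13 (24 h percentile 18.9). The shift had adjusted p = 0.00204, and adjusted p = 0.249 with an estimated correlation.

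The unfolded protein response genes differed little up to 12 h and were lower at 24 h. Both arrays entered that difference: against 2 h of the same arm the list was −0.54, −0.70 and 0.35 in BSA at 6, 12 and 24 h (percentile 99.1 at 24 h) and −0.29 in TNF-α at 24 h, on the array with the GAPDH gap of 6.28. Of 18 members 0 passed (0 adjusted over the list alone; 2 risen adjusted over the list alone from 2 to 12 h), and 8 were at least 2-fold lower at 24 h, with a median of −0.93 at percentile 0.01. XBP1 was 0.63 at 12 h and −2.59 at 24 h, DDIT3 0.44 and −2.09, and TRIB3 0.10 and −2.76. Camera called the list down over the 4 times (adjusted p = 0.00566) and not without the 24 h pair, where its direction was up (0.249), and over the 4 times adjusted p = 0.586 with an estimated correlation. Of the 15 TGF-beta targets 0 passed over the 4 times and ID1 fell from 2 to 12 h (1 fallen, and 4 risen and 2 fallen from 2 to 12 h, adjusted over the list alone). Its members went both ways: BAMBI, a decoy receptor, was 2.91 higher at 2 h, and TGFBI 1.06 higher at 6 h. This list was not called (adjusted p = 0.859); its test was down over the 4 times and up without the 24 h pair, where its median (−0.03) and mean (−0.17) were negative.

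Among epithelial junction and defence genes 1 member passed. Of 14 tight and adherens junction genes 0 passed over the 4 times, and CLDN1 alone rose from 2 to 12 h (1 adjusted over the list alone in both). CLDN1 was 2.81, 5.73, 4.68 and 3.56 higher, while OCLN was 0.63 and CDH1, the epithelial cadherin, −0.07 at 6 h. The list was not called (adjusted p = 0.0592). Of 21 redox and antimicrobial defence genes 0 passed (0 adjusted over the list alone) and the list was not called (adjusted p = 0.299). SOD2, the mitochondrial superoxide dismutase, was 0.60, 2.91, 3.61 and 1.82 higher, and the protease inhibitors PI3 and SLPI were 3.93 and 2.46 higher at 12 h, without passing.

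The other lists are given by their camera result over the 4 times, and 0 of their members passed in that fit. Those called up were class II antigen presentation (10 measured, adjusted p = 0.0293), kynurenine and prostaglandin enzymes (12, 0.00889), basal and myoepithelial markers (12, 0.0317), epithelial to mesenchymal transition (11, 0.0235) and immune cell markers (17, 0.0293). These had adjusted p = 0.594, 0.419, 0.594, 0.586 and 0.594 with an estimated correlation, and without the 24 h pair none was called. Camera does not match on expression level. Among random lists matched on it, their 24 h percentiles were 98.1, 97.3, 92.6, 91.0 and 78.3. Those called down were DNA replication (19, 0.00250), p53 targets (13, 0.0432) and ribosomal proteins (27, 0.0366), with adjusted p = 0.249 for each with an estimated correlation and none called without the 24 h pair. The 24 h percentiles of these lists among matched random lists were 6.3, 17.3 and 14.6. At least 2-fold lower at 24 h, beside the GAPDH gap of 6.28, were 8 of 27 ribosomal protein genes and 5 of 19 DNA replication genes, against 0 at the other times. Adjusted over the list alone 1 kynurenine and prostaglandin gene rose, and 0 of the other 7 lists' members passed.

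Not called were matrix metalloproteinases and inhibitors (18 measured, adjusted p = 0.0938), extracellular matrix and basement membrane (16, 0.282), aquaporins and fluid secretion (16, 0.0756), salivary acinar secretory products (16, 0.351), salivary ductal markers (13, 0.722), squamous differentiation (12, 0.633), fibroblast markers (11, 0.819), endothelial markers (10, 0.113), heat shock (12, 0.299), cholesterol synthesis (13, 0.968), hypoxia and glycolysis (19, 0.0764), metallothioneins (7, 0.259) and housekeeping reference genes (10, 0.852). Adjusted over the list alone 1 matrix and 1 hypoxia gene rose, 1 ductal and 1 fibroblast gene fell, and 0 passed in the other 9. From 2 to 12 h 1 member each of the matrix, cholesterol and hypoxia lists rose. MMP9, a gelatinase, was −0.05, −0.05, 0.79 and 2.60, and AQP5, the water channel of acinar cells, was 0.07, 0.08, 0.15 and 0.06. The median level of the acinar products in BSA was 3.29, below the lower quartile of all genes, 3.74. For the ductal, fibroblast and housekeeping lists the median was above 0 (0.03, 0.07 and 0.07) and the test's direction down, with a mean of −0.09, 0.05 and −0.01. Without the 24 h pair the squamous and metallothionein tests were up with means of −0.01 and −0.03. Relative to all genes, the medians of the ductal, epithelial to mesenchymal, DNA replication, cholesterol and housekeeping lists at 2 h, of the fibroblast list at 12 and 24 h and of the ductal and squamous lists at 24 h were at most 0.03 and changed sign after quantile normalisation again.

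Did the effect of TNF-α change with time? The genes with the strongest evidence were OAS3, an antiviral enzyme that senses double-stranded RNA, C1S, a complement protease, IFIH1, FAS and SP100, a nuclear body protein, all more different at later times, and PLAU, the urokinase-type plasminogen activator, in the other direction. OAS3 was 0.37, 1.80, 3.08 and 4.62 higher at 2, 6, 12 and 24 h, C1S was 0.12, 1.46, 3.19 and 4.79 higher, and PLAU was 2.56, 1.22, 0.73 and −0.22. The difference in slope per doubling of the hours was 1.18 ± 0.09 (SE, 8 arrays) for OAS3, 1.31 ± 0.13 for C1S, 1.19 ± 0.14 for IFIH1, 0.80 ± 0.09 for FAS, 0.82 ± 0.10 for SP100 and −0.75 ± 0.08 for PLAU. None passed. With limma 0 genes had an interaction past the threshold, 675 had an unadjusted p under 0.05 where chance gives 912, and the smallest adjusted p was 0.367, for OAS3. This model has no separate term for each time, so it does not pair the arrays by time. Changes shared by both arms that are not linear in log2 hours enter its residual. The 0 calls therefore do not show that the effect stayed the same over time.

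Within the TNF-α arm OAS3 rose with time, by 1.21 per doubling of the hours (adjusted p = 0.0438), against 0.04 in the BSA arm. It was the 1 gene past the threshold in that arm, with 1938 at an unadjusted p under 0.05. Without the 2, 6, 12 or 24 h pair the count was 0. It was also 0 after centring, with the mean of probe sets and with all probe sets tested, and 745 with time in hours, and its 24 h value is from the array with the GAPDH gap of 6.28. In the BSA arm limma called 0 genes, 654 had an unadjusted p under 0.05, and the smallest adjusted p was 0.985. The spread in this fit is shared by both arms and so includes the 24 h TNF-α array. The 0 calls therefore do not show that the BSA arm was stable, and 796 genes were at least 2-fold apart between BSA at 24 h and 2 h. That OAS3 passed in 1 arm does not show that the arms differ, and the test of the difference gave 0.367.

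How did the response look at each time? At 2 h the genes furthest above BSA were CXCL8 (7.88), TNFAIP3 (7.87), CCL20 (7.25), CCL2 (5.90) and EFNA1, an ephrin ligand (5.38). At 6 h CXCL10 (6.82) joined TNFAIP3 (7.48), CXCL8 (7.26), CCL20 (6.40) and CCL2 (5.96), and at 12 h the order was CXCL10 (6.96), TNFAIP3 (6.30), TNFRSF9 (5.46), CCL2 (5.09) and CLDN1 (4.68). At 24 h TNFAIP3 (6.11) was followed by CXCL11 (5.04), CD44 (4.84), the interferon-induced IFI44 (4.80) and C1S (4.79). These are values with no replicate check.

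The genes furthest below BSA at 2 h were ID1 (−2.46), SOX2 (−2.27), ID2 (−1.65), the stress-induced mTOR inhibitor DDIT4 (−1.25) and FAM43A (−1.19). At 6 h ID1 (−3.52), SOX2 (−3.17) and ID2 (−2.43) were joined by the chemokine scavenger ACKR3 (−2.74) and the growth factor GDF6 (−2.13). At 12 h they were ID2 (−3.30), the amino acid transporter SLC38A4 (−3.24), SOX2 (−2.81), ACKR3 (−2.78) and the transcription factor RFX7 (−2.24). At 24 h a different set stood lowest: the translation factor EEF1G (−6.84), the splicing factor TRA2A (−5.57), SERF2 (−4.69), the mRNA export factor ALYREF (−4.61) and the stress cytokine GDF15 (−4.56). These 5 genes lay between −0.37 and 0.25 at the earlier times. For GDF15 the BSA array read 3.06 at 2 h, under the lower quartile of all genes, 3.74, and 7.49 at 24 h, while TNF-α at 24 h was −0.38 against 2 h. A rise that the 24 h TNF-α array failed to register would look the same, so the GDF15 difference cannot be placed on 1 array. EEF1G, TRA2A, SERF2 and ALYREF were low on the 24 h TNF-α array, the one with the GAPDH gap of 6.28.

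Genes at least 2-fold apart numbered 98 at 2 h (90 higher, 8 lower), 322 at 6 h (252 and 70), 388 at 12 h (235 and 153) and 2329 at 24 h (1113 and 1216). The balance moved with the scaling, the fold threshold and the choice of probe sets: at 24 h 911 were higher and 1382 lower after centring and 893 and 1305 after quantile normalisation again, at 1.5-fold 493 were higher and 725 lower at 12 h, and 3232 and 2130 at 24 h, and with the mean of probe sets 454 and 1158 at 24 h. At 2, 6 and 12 h together 57 genes were at least 2-fold higher, and 36 of them also at 24 h. Lower at 2, 6 and 12 h were 4 (ID1, ID2, SOX2 and ZNF708), and of these ID2 also at 24 h.

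**Figure D4:**
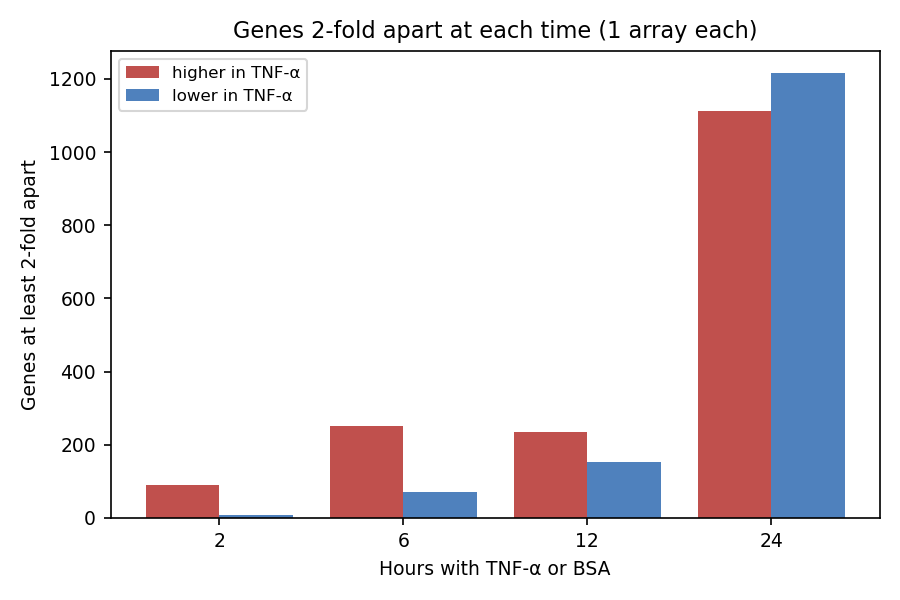
Number of genes at least 2-fold higher (red) or lower (blue) in TNF-α than in BSA at each time, from 1 array per treatment, among 18239 genes. Bars go from 90 and 8 genes at 2 h to 1113 and 1216 at 24 h.

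How alike were the responses at different times? The 6 h and 12 h responses were most alike, with 165 genes at least 2-fold higher at both (3.25 by chance) and 32 lower (0.587 by chance). Between 2 h and 6 h 76 genes were higher at both (1.24 by chance) and 4 lower (0.0307), and between 2 h and 12 h 58 (1.16) and 4 (0.0671). The genes at least 2-fold higher at all 3 times include TNFAIP3, CXCL8, CCL2 and ICAM1. The 24 h response shared 46, 143 and 143 higher genes with 2, 6 and 12 h (5.49, 15.4 and 14.3 by chance) and 2, 8 and 15 lower genes (0.533, 4.67 and 10.2 by chance), and 6, 16 and 25 genes were 2-fold apart in opposite directions. Across genes, which are not independent replicates, the correlation of TNF-α minus BSA was 0.575 between 2 and 6 h, 0.451 between 2 and 12 h, 0.704 between 6 and 12 h, and 0.114, 0.266 and 0.190 between 24 h and 2, 6 and 12 h. The mean over the 6 pairs of times was 0.383 (Spearman 0.191), 1 value for each of 6 comparisons and without a test.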

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

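Of the tests of the 24 h pattern, the overlap with the 12 h genes was chosen only after the result was seen, and the other 3 were written before. Outlying values were looked for in 52 series of 4 values, 12 of array measures within a treatment and 40 of list medians over the 4 times, and 10 stood apart from the other 3 values, where chance gives about 1 in 20, or 2.6. Within the TNF-α arm the 24 h array was far from the others in 5 measures that are not independent: its lower quartile was 3.51, its upper quartile 6.22, the gap between 3′ and 5′ signal 6.28 for GAPDH and 6.88 for ACTB, and its mean correlation with the other arrays 0.925. The medians of 5 lists at 24 h stood apart from those at 2, 6 and 12 h, beside a median of all genes of 0.20: endothelial markers 0.26 (percentile 60 among matched random lists), unfolded protein response −0.93 (0.01), metallothioneins 0.95 (99.9), TGF-beta targets 0.30 (73.4) and housekeeping reference genes 0.29 (87.9). Against 2 h of the same arm, these lists at 24 h were −0.058, 0.35, −0.68, −0.34 and −0.20 in BSA and 0.098, −0.29, 0.090, −0.62 and 0.12 in TNF-α. For the metallothioneins the larger change was on the BSA array. The TNF-α value is from the array with the GAPDH gap of 6.28, so that difference cannot be placed on 1 array. Among the 4040 probe sets without a single gene name, which the gene tests left out, 6 passed without the 24 h pair and 0 over the 4 times.

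At 24 h 2329 genes were at least 2-fold apart, against at most 388 at an earlier time. After centring 2293 genes were that far apart, 5.94 times the next highest time. This test decides little, since the gene medians at 24 h were 5.09 in BSA and 5.18 in TNF-α, so centring could move few genes. Quantile normalisation again was planned as an alternative and not as this test, and it also makes the spread equal. It left 2198, against at most 382 earlier, which argues against unequal scaling as the whole cause. A response that began by 12 h is argued against as the whole cause, since 55.1% of the 2329 genes had the same sign at 12 h, near the 55.4% of all genes and far from the 97.2% of the 12 h genes at 6 h. It stays open for a part: 143 genes were 2-fold higher at both times, 9.97 times the 14.3 of chance, and 15 lower (10.2 by chance), while the same-sign share was 45.7% among the higher and 63.7% among the lower genes. Loss of the 5′ parts of transcripts is a candidate explanation: probe sets of the same gene, which lie at different distances from the 3′ end, disagreed 2.95 times as much as at 12 h, the highest of the other times (median SD 0.418 over 7028 genes, against 0.102, 0.136 and 0.141 at 2, 6 and 12 h). The spread over all genes was also wider at 24 h (SD 0.733, against 0.384 at 12 h), and probe positions were not used. The disagreement alone therefore does not single out loss of the 5′ parts. A response that starts after 12 h was not tested and stays open, because 1 array per treatment cannot part it from the quality of that array's RNA.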

How the results depend on the processing

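Array quality weights were chosen only after the 24 h TNF-α array was seen to stand apart, and the other alternatives were planned. The alternatives were counted for the 135 genes picked by the naming rule and the 40 lists, not for all genes. For these genes 1493 values kept their direction and side of the threshold, 80 came to pass, 11 no longer passed and 14 reversed. For lists these were 336, 6, 73 and 18. A value that passed in neither fit also counts as kept. The mean correlation between times was 0.375 to 0.411 with other alternatives and 0.191 with Spearman, and the BSA slope count was 0 under each. NFKBIA was 3.21 to 3.32 higher under its alternatives, and its adjusted p ranged from 0.000162 to 0.117. Signal near the background, as for the acinar products (median 3.29), limits what the arrays can show.

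In place of the 3 genes over the 4 times, 1 was called with the mean of all probe sets, 1 with all probe sets tested, 6 with genes at or above the median level (fewer genes tested), 5 with trend and robust eBayes, 5 with no time term, 6 with log2 hours and 62 with array quality weights, which gave the 24 h pair a weight of 0.176 against 1.53 to 2.00. Leaving out 1 time gave 0 to 67, the highest without 24 h. The interaction count of 0 became 1 with time as rank. The TNF-α slope count of 1 became 0 with the mean of probe sets, 2 with the median level filter, 2 after quantile normalisation, 0 after centring, 0 with all probe sets, 3 with trend and robust eBayes, 12 with time as rank and 745 with time in hours, and ranged from 0 to 0 when 1 time was left out. By construction of the threshold, counts at 2, 6, 12 and 24 h were 209, 979, 1218 and 5362 at 1.5-fold and 51, 135, 151 and 874 at 3-fold; with the mean of probe sets they were 212 at 6 h, 233 at 12 h and 1612 at 24 h. By direction, the 24 h genes were 3232 higher and 2130 lower at 1.5-fold and 454 and 1158 with the mean of probe sets, and the 12 h genes 493 and 725 at 1.5-fold. The 24 lists became 0 with an estimated correlation, 3 with fry and 15 to 25 without 1 time. The 0 rests on 3 residual degrees of freedom and so decides little. Where the construction does not show it, the cause was not tested.

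Of the genes and lists that reversed, only the unfolded protein response list had been called. Leaving out 1 time gave the mean difference as −0.064 to 0.41 for PPP1R15A, −0.35 to 0.14 for KIF11, −0.099 to 0.34 for TNFRSF1A, −2.31 to 0.015 for EEF1G, −1.56 to 0.049 for GDF15, −0.69 to 0.084 for GPX1, −0.055 to 0.42 for CDH1, −0.57 to 0.56 for XBP1 and −0.58 to 0.26 for DDIT3. Array weights gave −0.0081 for CDH1, 0.46 for XBP1 and 0.18 for DDIT3. For lists the value is the median less that of all other genes, and the direction is that of the test, so a value may keep its sign where the test turned. Leaving out 1 time gave −0.0046 to 0.038 for cholesterol synthesis, −0.048 to 0.045 for housekeeping genes, −0.45 to 0.022 for the unfolded protein response, −0.25 to 0.068 for heat shock and −0.16 to −0.021 for TGF-beta targets. With fry and with no time term the value is that of the main fit, and only the direction of the test turned. Both turned it for TGF-beta targets (−0.094) and housekeeping genes (0.028). With no time term it also turned for ductal markers (−0.016) and cholesterol synthesis (0.016). The mean of probe sets gave −0.00068 for ductal markers and −0.090 for cholesterol synthesis, the median level filter 0.11 for housekeeping genes, and quantile normalisation −0.022 for acinar products, 0.021 for squamous differentiation and 0.070 for housekeeping genes. The causes were not tested.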

Other observations

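In this part the test of RNA quality and the 24 h test of drift for the interferon-stimulated genes and the test of the ID1 probe sets were chosen only after the result was seen, and the genes named for the BSA arm were chosen after their values were seen. With time in the BSA arm limma called 0 genes, with 654 at an unadjusted p under 0.05 where chance gives 912, so what follows is single values. Against BSA at 2 h, 263 genes were at least 2-fold apart in BSA at 6 h, 95 at 12 h and 796 at 24 h, values from 1 array each with no replicate check. The immediate early transcription factor EGR1 was −5.01 at 6 h and −4.76 at 12 h, and the growth-related CCN2 (−2.52 at 6 h), TIPARP (−2.42), the MAP kinase phosphatase DUSP6 (−2.23) and the stress factor ATF3 (−2.15) were lower with it. The AP-1 and immediate early list had a median of −0.61 at 6 h, −1.06 at 12 h and −0.51 at 24 h against 2 h, the metallothioneins, which bind zinc and copper, 0.65, 0.62 and −0.68, and the heat shock list 0.26, 0.61 and −0.78.

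On the BSA array at 24 h some genes that stand out in the comparison with TNF-α differed from BSA at 2 h. ID1 was −4.91 against BSA at 2 h, ID2 −4.05, ID3 −2.61 and BMP4 −2.35, while the stress-induced GDF15 was 4.43, the unfolded protein response factor DDIT3 3.10 and TRIB3 1.86 higher. The 24 h differences from BSA were 0.91 for ID1 and −4.56 for GDF15. Cholesterol synthesis genes had a median of −0.77 and proliferation genes −0.59 at 24 h. Of the 335 genes at least 2-fold higher in TNF-α at 2, 6 or 12 h, 41 had their largest difference at 2 h, 150 at 6 h and 144 at 12 h. At 12 h 158 genes were 2-fold higher and 145 lower that were under 1.5-fold apart at 2 h, and 15 genes 2-fold higher at 2 h were under 1.5-fold at 12 h.

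Interferon-stimulated genes were further above BSA at later times. Poor RNA on the 24 h array is argued against as the source of the rise, since without it the 12 h difference already exceeded the 2 h difference by a median of 1.57 (quartiles 1.08 and 2.55, higher in 27 of 28 members). A drift of the controls is argued against up to 12 h, since the members' median change in BSA from 2 to 12 h was 0.127 (quartiles −0.06 and 0.53), where the explanation needs a fall; at 24 h it stays open for a part, as BSA was −0.34 against 2 h (percentile 0.01 of matched random lists) and TNF-α 1.58. Interferon made by the cells stays a candidate explanation: the largest difference among 5 interferon genes at 2 and 6 h was 0.238, for IFNG at 6 h, under the bound for excluding it, which was not applied because all 5 lay at or below 3.30, under the lower quartile of all genes, 3.74, where the arrays could miss a small amount of transcript.

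ID1 and SOX2 fell from 2 to 12 h, and ID2 was lower at the same times without passing. A single misbehaving probe set is argued against for ID1, since its 3 probe sets were all at or below −2.03; for the 3 genes together 85.7% of 7 probe sets were lower, which met the bound for excluding it but decides nothing for ID2, with 1 probe set, or SOX2, where 1 of 3 carried the difference. Lower BMP signalling may underlie the pattern, as ID genes are known BMP targets: 17 other BMP targets had a median of −0.09 at 6 h, at percentile 4.04 of matched random lists, under the bound of 5 set beforehand. It was still left open, because their percentile was 90.8 at 2 h, when ID1 was already −2.46, and 15.1 at 12 h. The members at the median lay near the background, beside a lower quartile of all genes of 3.74. At 6 h ID4 read 3.75 in BSA and 3.66 in TNF-α, and at 12 h SMOC2 read 3.60 and 3.57. Among members at higher levels, ID3 and the ligand BMP4 were −0.39 and −0.78 at 6 h, and MSX1 and the BMP antagonist GREM1 0.29 and 0.34. The list thus mixes targets with ligands and antagonists of BMP, so its median does not measure targets alone. A direct effect of TNF-α on ID1, ID2 and SOX2 was not tested.

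Other splits of the 8 arrays into 4 and 4 bear on the counts. Of 35 splits 3 could not be fitted with the time term, and among the other 32 only the real split, 1 of 32, gave as many as 3 genes (highest other 0) or as many as 24 lists (highest other 18). The arrays pair by time, and the real split is 1 of 8 that part the arrays of each time, which are too few for a share under 0.05 (highest other 0 genes and 18 lists); the other 24 leave both arrays of some times together. Without the 24 h pair the real split gave 67 genes and the highest other 0, and 10 splits are too few for a share under 0.05. For the interaction with time the real split gave 0 genes, which all 35 splits reach by construction, so that count decides nothing. The arrays of 2 and 12 h against those of 6 and 24 h gave 1081, which points to a structure of the samples. That split follows time itself, and what lies behind it was not tested.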
